A study of Mus musculus with 10 samples.

How the data were processed

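Hippocampal RNA of 10 mice aged 6 months was sequenced, 5 wild type (WT) and 5 of the genotype labelled TfamAKO, with 1 library per mouse. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a stranded mRNA kit. Tfam encodes a protein that packages mitochondrial DNA (mtDNA) and is needed for its transcription. The series title speaks of astrocytic mitochondria, and the labels do not say which part of Tfam was deleted or in which cells. The labels give no sex, litter or batch.

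The authors deposited 2 tables over the same 20156 gene rows. The first holds unnormalized estimated counts. The submitters' processing notes name Salmon, with no version, and DESeq2 version 1.26.0. The deposited counts were all whole numbers, so the rounding of estimated counts changed no value. The second table holds normalized values, treated here as a signal because how the authors made them is not given in the sources used here. The ratio of the deposited normalized signal to the count differed between genes within a library as well as between libraries. Its median ran from 0.787 in TfamAKO 4 to 1.36 in WT 1. In WT 1 its 5th and 95th percentiles were 1.14 and 1.63. The genome build and annotation are not given in the sources used here, so no coordinates are printed. Gene symbols are those of the table. Of its rows, 17025 (84.5%) matched a symbol of GENCODE M21, 2880 carried an Ensembl-type name, and 24 carried names that a spreadsheet had turned into dates. The date-named rows stayed in the tests and are not named.

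Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 16180 and removed 3976. Library sizes were scaled by TMM factors, and groups were compared by the two-sided quasi-likelihood F test with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are TfamAKO minus WT and carry standard errors (SE), taken as the absolute log2 fold change divided by the square root of F. Levels are CPM (counts scaled by the effective library size) as mean ± SD over 5 mice. Where all WT libraries were at 0, the fold was computed against a floor of 3 counts over the WT group, which covers counting error only. Reads are not independent molecules, because the libraries carry no stated molecular identifiers.

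Before the data were examined, 44 gene lists were fixed, together with the tests, the alternatives and the rule for naming genes. The rule names Tfam, the 10 genes with the largest rise and the 10 with the largest fall, and up to 4 members with the smallest p of each list. The largest changes were taken from genes past the threshold with an average of at least 1 CPM and every TfamAKO library on the same side of the WT mean. Other genes named were chosen after their values were seen and are said to be so. The 43 lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2. The same lists were tested with the correlation estimated from the data, with fry, and by a two-sided exact permutation test of the list score (mean log2 CPM of the members in a library) over all 252 assignments of 5 and 5 libraries. The smallest p this test can give is 0.00794. The share of counts from the 13 mRNAs encoded by mtDNA was compared by the same exact test.

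Alternatives were DESeq2 size factors, upper-quartile scaling, 2 other filters, the DESeq2 1.42.0 Wald test, limma-voom with and without sample weights, a robust fit, glmTreat against a 1.2-fold change, and limma on the log2 of the deposited normalized values with pseudocounts of 0.5, 1 and 5. Further alternatives were thinned counts, 1 surrogate variable (sva 3.50.0), a replicate block, scaling without abundant genes, and leaving out each library. Alternatives added after the data were seen used the authors' factors as offsets, or dealt with libraries that held Y-linked or choroid plexus transcripts. Transcript length and GC content came from the longest GENCODE M21 transcript of each symbol.

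The steps were tested on simulated data with the real means and library sizes of the 16180 genes and 200 changed genes of at least 1 CPM. Dispersions were those of the fitted trend over the average level, not of each gene. The comparison of WT and TfamAKO recovered 18% of 50 genes changed 1.25-fold, 66% of 50 changed 1.5-fold, 88% of 50 changed 2-fold and 100% of 50 changed 4-fold. Of 142 calls, 6 (4.23%) were false, and with no changed gene there were 0 calls. These genes were drawn independently, so the simulation does not cover correlation between genes. Nor does it cover genes that vary more than the trend or a share of changed genes as large as that called in the data. Total counts ran from 16584245 to 28675367 per library. Within groups, libraries correlated at 0.970 to 0.991 (Pearson's r of log2 CPM across genes, which are not independent replicates), and no pair agreed within sampling noise.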

Results

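RNA from the hippocampus of 5 WT and 5 TfamAKO mice was compared at 6 months of age. Total counts per library ran from 16584245 to 26032470 in WT and from 19558377 to 28675367 in TfamAKO. The comparison asks which transcripts differ in hippocampus between the genotypes, and the series title places the question in the mitochondria of astrocytes, fatty acid degradation and neuroinflammation.

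Tfam, the targeted gene, was measured at 31.7, 33.0, 20.6, 32.5 and 30.4 CPM in WT 1 to 5 and at 23.6, 22.7, 19.6, 23.1 and 23.4 CPM in TfamAKO 1 to 5. Its level fell in TfamAKO (log2 fold change -0.40 ± 0.12, edgeR adjusted p = 0.0204), while WT 3 lay within the TfamAKO range. The mRNAs encoded by mtDNA, which are subunits of the respiratory chain and ATP synthase, made up 5.85% ± 0.693 of counts in WT (SD, n = 5) and 4.41% ± 0.297 in TfamAKO (SD, n = 5). The difference of -1.44 percentage points had p = 0.00794 in a two-sided exact permutation test, the smallest p this test can give. Tfam lost its call in the authors' normalized values (log2 fold change -0.28, limma adjusted p = 0.117). It also lost it without WT 2 (edgeR adjusted p = 0.0580), WT 4 (0.0504) or TfamAKO 3 (0.0554), and under other alternatives listed in the closing section.

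**Figure D1:**
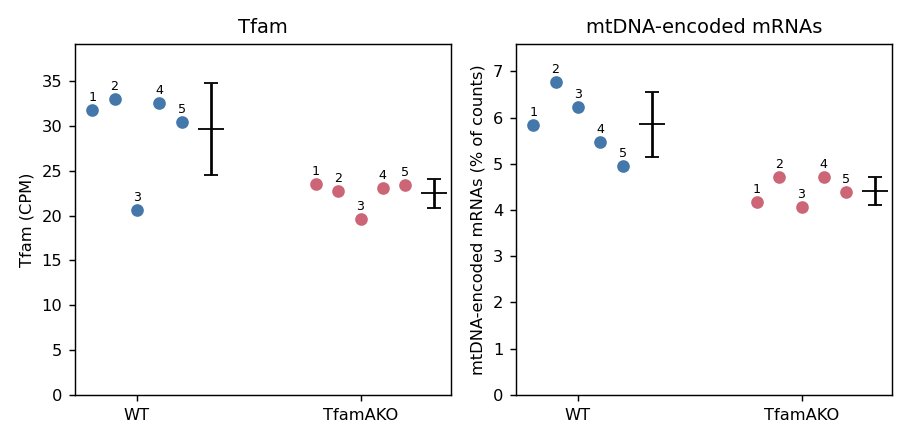
Tfam in CPM (left) and the share of counts from mtDNA-encoded mRNAs in percent (right) for each library, numbered by replicate, with the group mean and SD beside the points. WT 3 is the WT library within the TfamAKO range of Tfam, and the shares of the groups do not overlap.

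Of 16180 genes tested, 6048 (37.4%) differed between the genotypes, 3369 higher and 2679 lower in TfamAKO (edgeR, adjusted p threshold 0.05). More than 2-fold changes were found for 982 higher and 321 lower genes, and more than 4-fold changes for 224 and 68. The groups did not overlap for 3873 genes (23.9%), against 0.794% by chance. On the first principal component of log2 CPM (53.7% of variance), WT libraries lay between -46.2 and -34.8, TfamAKO 1 at 12.2 and the other TfamAKO libraries between 37.1 and 52.7. Y-linked Kdm5d was at 22.7 and 22.4 CPM in TfamAKO 4 and 5 and under 1 CPM elsewhere, and Xist, chosen after its values were seen, was at 0.141 and 0 CPM there and between 200.6 and 467 CPM in the other 8 libraries. By these transcripts TfamAKO 4 and 5 were male and the other 8 mice, all WT included, female, so sex was unbalanced between the genotypes. Without TfamAKO 4 and 5, 4931 genes passed. Without WT 3, 4 and 5, which held choroid plexus transcripts, 2752 passed, 2002 higher and 750 lower.

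**Figure D2:**
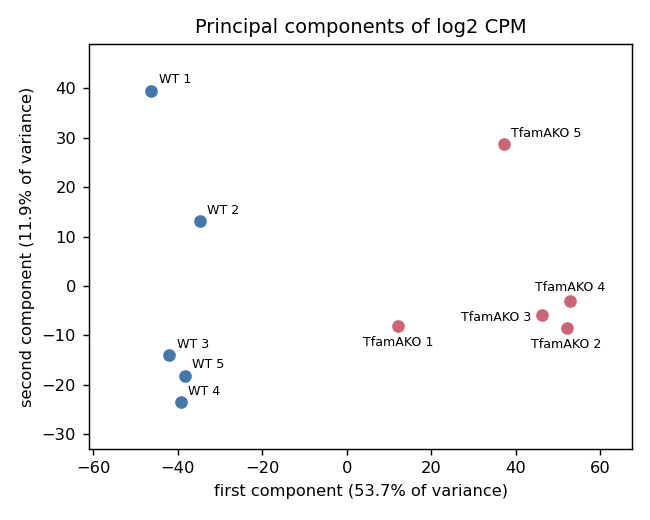
The first and second principal components of log2 CPM for the 10 libraries, with the share of variance on each axis. TfamAKO 1 lies at 12.2 on the first component, between the WT libraries and the other TfamAKO libraries.

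The genes with the largest rise included a protease inhibitor, a transglutaminase and secreted stress factors. Serpina3m and Adm2 (adrenomedullin 2) had 0 counts in all WT libraries and were at least 296-fold and 77.6-fold higher in TfamAKO. Tgm1 (transglutaminase 1, log2 fold change 8.14 ± 0.36, edgeR adjusted p = 4.00e-08), Cdsn (corneodesmosin, log2 fold change 6.45 ± 0.25, edgeR adjusted p = 1.77e-08) and Klk6 (kallikrein-related peptidase 6, log2 fold change 5.65 ± 0.40, edgeR adjusted p = 1.89e-06) rose in every TfamAKO library. Gdf15, a secreted stress cytokine, went from 0.270 ± 0.323 CPM in WT to 28.5 ± 10.2 CPM in TfamAKO (log2 fold change 6.73 ± 0.47, edgeR adjusted p = 1.54e-06). Ostn (7.59 ± 0.45), Clca3a1 (5.83 ± 0.52), Cyb5r2 (5.64 ± 0.39) and the stress-induced pseudokinase Trib3 (5.64 ± 0.24) completed the 10 on the log2 scale. Serpina3 genes form a family of close copies, so reads shared between them leave the level of Serpina3m uncertain.

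Of the 10 genes with the largest fall, 9 are expressed in choroid plexus, among them Ttr (transthyretin), Kcne2 (-5.05 ± 1.14) and Folr1 (-4.28 ± 0.88). Ttr went from 2319 ± 2256 CPM in WT to 44.4 ± 36.4 CPM in TfamAKO (edgeR adjusted p = 0.00420). The WT level of these genes came mostly from 3 libraries. Ttr was at 5146, 3801 and 2511 CPM in WT 3, 4 and 5, at 14.3 and 122 CPM in WT 1 and 2, and at 15.5 to 107 CPM in TfamAKO. In the list of choroid plexus and ependyma, 1 of 22 tested genes rose and 15 fell (1 and 15 adjusted over the list alone), with a median log2 fold change of -2.97 (camera adjusted p = 0.00883, and adjusted p = 0.595 with an estimated correlation). The list did not pass the exact permutation test of its list score (adjusted p = 0.130) or fry (0.118). It lost its camera call without TfamAKO 4 and 5 (adjusted p = 0.0508). The tenth gene, Rtl3, fell in every TfamAKO library (log2 fold change -3.61 ± 0.38, edgeR adjusted p = 3.34e-05).

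**Figure D3:**
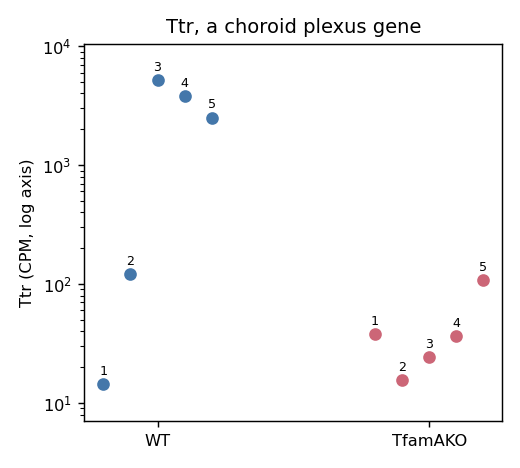
Ttr in CPM on a log axis for each library, numbered by replicate. WT 3, 4 and 5 lie between 2511 and 5146 CPM, and the other 7 libraries between 14.3 and 122 CPM.

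Genes of the mitochondrial integrated stress response, which include targets of the transcription factor ATF4 and enzymes of serine and one-carbon metabolism, rose together. In this list 29 of 31 tested genes rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 fold change of 1.87 (camera adjusted p = 3.73e-22, and adjusted p = 0.0796 with an estimated correlation). Aldh1l2, a mitochondrial enzyme of folate metabolism, went from 3.24 ± 0.564 CPM in WT to 33.8 ± 2.53 CPM in TfamAKO (log2 fold change 3.38 ± 0.12, edgeR adjusted p = 8.26e-09). Aldh18a1 of proline synthesis (1.95 ± 0.07), the translation repressor Eif4ebp1 (4.16 ± 0.16) and Nupr1 (4.45 ± 0.18) rose on the log2 scale. Of mitochondrial proteases and chaperones, 10 of 18 tested genes rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.353 with an estimated correlation), with Lonp1 (1.03 ± 0.09) and Hspa9 (1.36 ± 0.12) at the head. Genes of the neurotrophic and antioxidant response gave 16 of 23 tested genes higher and 2 lower past the threshold (16 and 2 adjusted over the list alone, camera adjusted p = 1.49e-05, and adjusted p = 0.270 with an estimated correlation). Heme oxygenase Hmox1 went from 5.26 ± 0.840 CPM in WT to 149 ± 36.9 CPM in TfamAKO (log2 fold change 4.83 ± 0.20, edgeR adjusted p = 1.81e-08), and the cystine transporter Slc7a11 rose by 2.12 ± 0.21 on the log2 scale.

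Transcripts of the respiratory chain fell in part. Of mtDNA-encoded mRNAs, 0 of 13 tested genes rose and 11 fell (0 and 12 adjusted over the list alone, camera adjusted p = 1.30e-05, and adjusted p = 0.357 with an estimated correlation). The smallest p were those of mt-Nd2 (log2 fold change -0.78 ± 0.10, edgeR adjusted p = 0.000153) and mt-Nd4 (-0.54 ± 0.09). Among nuclear-encoded respiratory chain subunits 2 of 52 tested genes rose and 18 fell (2 and 18 adjusted over the list alone), with a median log2 fold change of -0.10 (camera adjusted p = 0.0106, and adjusted p = 0.636 with an estimated correlation), and Ndufa1 (-0.51 ± 0.08) and Cox6c (-0.33 ± 0.05) fell. The nuclear-encoded list passed the exact permutation test of its list score (adjusted p = 0.0253) and not fry (0.0676). It lost its camera call without TfamAKO 5 (adjusted p = 0.0971) and without TfamAKO 4 and 5 (0.0559). After trends with transcript length and GC content were removed within each library, a step chosen after the data were seen, its median difference of log2 CPM went from -0.10 (SE 0.03) to -0.17 (SE 0.03). In the list of mtDNA maintenance and expression 2 of 23 tested genes rose and 2 fell (0 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.807, and adjusted p = 0.842 with an estimated correlation). Its median of -0.02 changed sign under 2 of 6 scalings.

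Genes of fatty acid oxidation rose. In the list of fatty acid beta-oxidation 24 of 35 tested genes rose and 0 fell (24 and 1 adjusted over the list alone), with a median log2 fold change of 0.42 (camera adjusted p = 2.07e-06, and adjusted p = 0.353 with an estimated correlation). Eci2 went from 34.3 ± 3.17 CPM in WT to 88.9 ± 9.20 CPM in TfamAKO (log2 fold change 1.37 ± 0.09, edgeR adjusted p = 7.03e-07), and Acadl (1.34 ± 0.14), Decr1 (1.19 ± 0.14) and Hadh (1.06 ± 0.14), enzymes of the same pathway, also rose. In lipid droplet and fatty acid storage 11 of 24 tested genes rose and 1 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.0209, and adjusted p = 0.270 with an estimated correlation). The droplet coat gene Plin2 (1.81 ± 0.15) and the lipase inhibitor Angptl4 (2.15 ± 0.18) were higher. Cholesterol synthesis did not pass camera, and 2 of 24 tested genes rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.129, and adjusted p = 0.691 with an estimated correlation). Without TfamAKO 1 that list passed (camera adjusted p = 0.00857). Insig1 (-0.61 ± 0.13) and Idi1 (-0.57 ± 0.14) were lower and Hsd17b7 (0.74 ± 0.07) higher. Glycolysis and lactate did not pass camera either, with 6 of 27 tested genes higher and 8 lower past the threshold (7 and 9 adjusted over the list alone, camera adjusted p = 0.482, and adjusted p = 0.802 with an estimated correlation). The exact permutation test of its list score did pass, upward (difference 0.08, adjusted p = 0.0353), while the camera direction was downward and fry gave 0.982. Its median log2 fold change was -0.12 and its mean 0.09, with Pfkfb3 (1.36 ± 0.11) higher and Aldoc (-0.81 ± 0.11) lower.

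Astrocyte reactivity genes rose in all TfamAKO libraries, whereas astrocyte identity genes moved both ways. Of the pan-reactive list, 15 of 17 tested genes rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 2.82 (camera adjusted p = 1.21e-12, and adjusted p = 0.204 with an estimated correlation). Osmr, the oncostatin M receptor, went from 6.25 ± 1.18 CPM in WT to 126 ± 17.7 CPM in TfamAKO (log2 fold change 4.32 ± 0.14, edgeR adjusted p = 8.26e-09), and the intermediate filament gene Vim (4.01 ± 0.20) and Serpina3n (3.54 ± 0.20) rose. Gfap, chosen after its values were seen, went from 447 ± 69.6 CPM in WT to 2093 ± 498 CPM in TfamAKO (log2 fold change 2.23 ± 0.17, edgeR adjusted p = 2.65e-06). Of the A1-type list 10 of 13 tested genes rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000238, and adjusted p = 0.322 with an estimated correlation), and of the A2-type list 10 of 12 tested genes rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 2.80e-07, and adjusted p = 0.204 with an estimated correlation). The A1-type list shares H2-T23, H2-D1 and Psmb8 with MHC class I, Serping1 and C3 with complement, and Gbp2 and Iigp1 with interferon-stimulated genes. Levels in whole hippocampus do not tell which cells carry these transcripts. Among astrocyte identity genes 10 of 36 tested genes rose and 15 fell (10 and 15 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0813, and adjusted p = 0.704 with an estimated correlation), except without WT 1 (0.0246), TfamAKO 1 (0.0492) or TfamAKO 2 (0.0471). The amino acid transporter Slc7a10 (-2.42 ± 0.17) and Mfge8 (-1.14 ± 0.13) fell, and Aldh1l1 (1.29 ± 0.10) and Pla2g7 (1.16 ± 0.11) rose. Chosen after their values were seen, the glutamate transporter gene Slc1a2 (-0.66 ± 0.13) and glutamine synthetase Glul (-0.57 ± 0.10) fell, and Slc1a3 (0.55 ± 0.11) and Aqp4 (0.87 ± 0.13) rose.

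**Figure D4:**
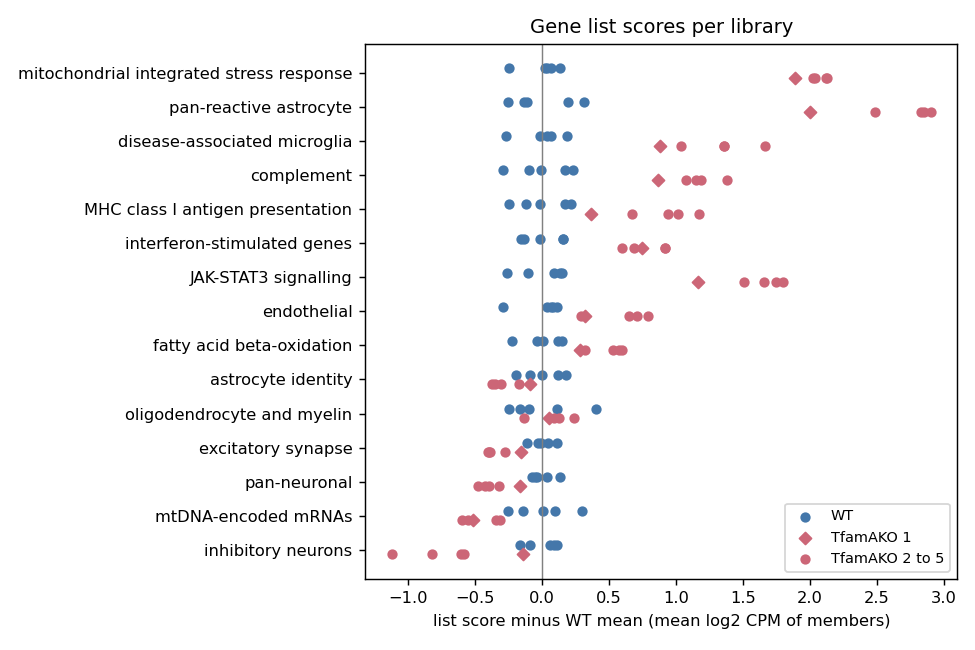
List scores per library (mean log2 CPM of the members, minus the WT mean) for 15 gene lists, with TfamAKO 1 as a diamond. The stress response score of TfamAKO 1 was 1.89 and those of the other TfamAKO libraries 2.02 to 2.13, while its inhibitory neuron score was -0.14 and theirs ran from -1.12 to -0.59.

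JAK-STAT3 signalling and matrix genes rose with them. For JAK-STAT3 signalling 14 of 22 tested genes rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 2.36e-07, and adjusted p = 0.215 with an estimated correlation). Stat3 (1.67 ± 0.12) and the cytokines Lif (3.43 ± 0.28) and Clcf1 (4.64 ± 0.39) were higher. Of this list, Stat3 and Clcf1 also belong to the A2-type list and Osmr to the pan-reactive list. For extracellular matrix and glial scar 16 of 29 tested genes rose and 2 fell (17 and 4 adjusted over the list alone, camera adjusted p = 0.00186, and adjusted p = 0.270 with an estimated correlation), led by tenascin C gene Tnc (3.64 ± 0.24) and Cd44 (2.82 ± 0.22).

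Microglial and immune genes were higher in TfamAKO. Of homeostatic microglia genes 15 of 25 tested genes rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.47e-05, and adjusted p = 0.270 with an estimated correlation), and of disease-associated microglia genes 26 of 33 tested genes rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 2.19e-10, and adjusted p = 0.270 with an estimated correlation). Among the members with the smallest p were Cx3cr1 (0.94 ± 0.07) and Trem2 (1.17 ± 0.11) in the first list and Itgax (4.19 ± 0.35) and Gpnmb (2.96 ± 0.25) in the second. Trem2 is a member of both lists. For complement 15 of 19 tested genes rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 2.36e-07, and adjusted p = 0.204 with an estimated correlation), and C4b went from 69.1 ± 9.97 CPM in WT to 522 ± 60.8 CPM in TfamAKO (log2 fold change 2.92 ± 0.12, edgeR adjusted p = 1.81e-08). C4b has a close copy, so shared reads leave its level uncertain. For MHC class I antigen presentation 14 of 19 tested genes rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 2.13e-06, and adjusted p = 0.322 with an estimated correlation). B2m (0.72 ± 0.11) and Tap2 (1.01 ± 0.13) were higher. MHC class II antigen presentation did not pass camera, with 3 of 9 tested genes higher and 0 lower past the threshold (3 and 0 adjusted over the list alone, camera adjusted p = 0.0610, and adjusted p = 0.416 with an estimated correlation). The class II list passed fry (adjusted p = 0.00287) and not the exact permutation test of its score (0.176). It did pass camera without WT 3, 4 and 5 (adjusted p = 0.000372), with the choroid plexus score (0.000933) or Y-linked expression (0.0289) as covariate, and without TfamAKO 4 and 5 (0.0329). It also passed with no filter on low counts (0.0255), with the authors' normalized values (0.0453), and without WT 3 (0.0395), WT 4 (0.0367), WT 5 (0.0321) or TfamAKO 5 (0.0468) alone. Among interferon-stimulated genes 24 of 46 tested genes rose and 0 fell (31 and 0 adjusted over the list alone, camera adjusted p = 1.98e-09, and adjusted p = 0.204 with an estimated correlation). Gbp3 (1.61 ± 0.12) and Ifitm3 (1.85 ± 0.18) were higher. In the list of cytokines, chemokines and NF-kB 20 of 30 tested genes rose and 3 fell (22 and 3 adjusted over the list alone, camera adjusted p = 1.41e-06, and adjusted p = 0.270 with an estimated correlation). Nfkb2 (2.23 ± 0.15) and Tnfrsf1a (2.55 ± 0.17) were higher.

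Lists of blood and vessel cells rose in part. For monocytes and neutrophils 4 of 6 tested genes rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.0239, and adjusted p = 0.270 with an estimated correlation). The members that rose were S100a4, Fn1, Vcan and Ly6c2, and the matrix genes Fn1 and Vcan are not restricted to these cells. The list lost its camera call with genes shared between lists removed (adjusted p = 0.221) and without WT 3, 4 and 5 (0.0740). It also lost it with the choroid plexus score (0.0658) or Y-linked expression (0.0533) as covariate and with the replicate block (0.0505). For border-associated macrophages 4 of 7 tested genes rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.416 with an estimated correlation). Siglec1 (2.31 ± 0.44) and Stab1 (0.51 ± 0.11) were higher. Of the T and B lymphocyte list only Lck was tested, with log2 fold change 0.68 ± 0.26, edgeR adjusted p = 0.0540 (1 and 0 adjusted over the list alone). For erythrocyte genes 0 of 6 tested genes rose and 0 fell (0 and 0 adjusted over the list alone) in edgeR (camera adjusted p = 0.269, and adjusted p = 0.634 with an estimated correlation). Among endothelial genes 15 of 24 tested genes rose and 3 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.00162, and adjusted p = 0.420 with an estimated correlation). Vwf (2.06 ± 0.28) was higher and Mfsd2a (-0.67 ± 0.09) lower. For pericyte, mural and fibroblast genes 7 of 24 tested genes rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00992, and adjusted p = 0.539 with an estimated correlation), and the list passed neither the exact permutation test of its score (adjusted p = 0.103) nor fry (0.0506).

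Neuronal transcripts were lower in TfamAKO. Of pan-neuronal genes 0 of 24 tested genes rose and 16 fell (0 and 18 adjusted over the list alone), with a median log2 fold change of -0.36 (camera adjusted p = 1.02e-06, and adjusted p = 0.270 with an estimated correlation), and the neurofilament gene Nefh (log2 fold change -0.84 ± 0.12, edgeR adjusted p = 0.000294) and Snap25 (-0.41 ± 0.07) fell. For excitatory synapse genes 1 of 29 tested genes rose and 14 fell (1 and 16 adjusted over the list alone, camera adjusted p = 4.39e-05, and adjusted p = 0.322 with an estimated correlation). The scaffold genes Shank1 (-0.58 ± 0.09) and Homer1 (-0.66 ± 0.10) were lower. Among inhibitory neuron genes 0 of 24 tested genes rose and 13 fell (0 and 19 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 2.07e-06, and adjusted p = 0.332 with an estimated correlation). The neuropeptide genes Cck (-0.68 ± 0.07) and Sst (-0.95 ± 0.18) fell. Relative to the WT mean, the inhibitory neuron score of TfamAKO 1 was -0.14, within the WT range of -0.16 to 0.11. In presynaptic vesicle machinery 1 of 30 tested genes rose and 14 fell (1 and 15 adjusted over the list alone, camera adjusted p = 0.000325, and adjusted p = 0.270 with an estimated correlation). Cplx1 (-0.53 ± 0.08) was lower. Activity-regulated immediate early genes did not pass, with 5 of 27 tested genes higher and 5 lower past the threshold (5 and 5 adjusted over the list alone, camera adjusted p = 0.982, and adjusted p = 0.991 with an estimated correlation), a median of 0.11, a mean of 0.04 and a downward test direction. Arc (-1.38 ± 0.30) and Nr4a2 (-1.11 ± 0.15) fell while Fos (1.49 ± 0.39) rose.

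Markers of hippocampal fields fell in part, those of the CA lists in about the share of all tested genes. In the dentate gyrus list 2 of 16 tested genes rose and 7 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.0459, and adjusted p = 0.456 with an estimated correlation). Calb1 (log2 fold change -1.22 ± 0.12, edgeR adjusted p = 2.52e-05) and Dsp (-2.54 ± 0.27) were lower. The dentate gyrus list lost its camera call without WT 3, 4 and 5 (adjusted p = 0.161), without TfamAKO 4 and 5 (0.103), and with the choroid plexus score (0.162) or Y-linked expression (0.0562) as covariate. It also lost it with the replicate block (0.0632), with genes shared between lists removed (0.0610), and without WT 3 (0.0711), WT 4 (0.0588), WT 5 (0.0551) or TfamAKO 5 (0.134) alone. For CA1 pyramidal genes 0 of 12 tested genes rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.0395, and adjusted p = 0.270 with an estimated correlation), and for CA3 and CA2 pyramidal genes 0 of 14 tested genes rose and 2 fell (0 and 2 adjusted over the list alone), the latter list not passing camera (camera adjusted p = 0.191, and adjusted p = 0.613 with an estimated correlation) or fry (0.148) but passing the exact permutation test of its score (difference -0.20, adjusted p = 0.0440). The CA1 list lost its camera call with shared genes removed (adjusted p = 0.0508) and with the choroid plexus score as covariate (0.0523). Over all tested genes 2679 of 16180 fell, so the counts of fallen CA genes were near that share. Relative to the WT mean, the dentate gyrus score was -0.85 in TfamAKO 5 and -0.44 to -0.21 in the other TfamAKO libraries. The CA1 score was -0.51 in TfamAKO 5 and -0.36 to -0.18 in the others. On the same scale, the CA3 and CA2 score was lowest in TfamAKO 5 (-0.49) and was -0.18 and -0.20 in TfamAKO 2 and 3. In TfamAKO 1 and 4 the CA3 and CA2 score was -0.05, within the WT range of -0.10 to 0.09. Adult neurogenesis did not pass, with 7 of 21 tested genes higher and 3 lower past the threshold (7 and 4 adjusted over the list alone, camera adjusted p = 0.916, and adjusted p = 0.959 with an estimated correlation), a median of -0.15 and a mean of 0.16. Relative to the WT mean, the neurogenesis score was 0.59 in TfamAKO 1 and -0.21 to 0.10 in the other TfamAKO libraries. The intermediate filament gene Nes went from 9.94 ± 1.42 CPM in WT to 91.7 ± 31.6 CPM in TfamAKO (log2 fold change 3.20 ± 0.27, edgeR adjusted p = 5.95e-06). Nes had the largest rise of the neurogenesis list and is also a member of the pan-reactive astrocyte list, so its rise is not particular to neurogenesis. The spillover list of thalamus, striatum and neocortex did not pass, with 6 of 20 tested genes higher and 3 lower past the threshold (6 and 3 adjusted over the list alone, camera adjusted p = 0.702, and adjusted p = 0.830 with an estimated correlation). Its score was highest in TfamAKO 5 (0.19 above the WT mean), the library lowest for the field lists, and a difference in dissection was not tested.

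Oligodendrocyte lists did not pass camera and held genes that moved both ways. Of oligodendrocyte and myelin genes 9 of 28 tested genes rose and 6 fell (10 and 8 adjusted over the list alone, camera adjusted p = 0.435, and adjusted p = 0.853 with an estimated correlation). Cldn11 (1.58 ± 0.15) was higher and Hapln2 (-1.65 ± 0.16) lower. Of the 6 that fell, Enpp2 is also a choroid plexus gene and was high in the WT libraries with choroid plexus transcripts. For oligodendrocyte precursors 6 of 17 tested genes rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.138, and adjusted p = 0.613 with an estimated correlation), and this list passed fry (adjusted p = 0.00863) and the exact permutation test of its score (difference 0.30, adjusted p = 0.0353). Ednrb (2.90 ± 0.16) was higher and Rlbp1 (-1.42 ± 0.17) lower. The precursor list had a median log2 fold change of 0.16 and a mean of 0.32, and Ednrb was its highest member. The upward score therefore leaned in part on Ednrb, and the list was not tested without it. Among cytosolic ribosomal protein genes 20 of 40 tested genes rose and 1 fell (24 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000125, and adjusted p = 0.595 with an estimated correlation). After the length and GC trends were removed, the median difference of log2 CPM of the ribosomal list went from 0.19 (SE 0.03) to 0.07 (SE 0.03), and its camera adjusted p from 0.000243 to 0.0374, so most of its rise went with these trends. In the sex-linked list 1 of 6 tested genes rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.782, and adjusted p = 0.853 with an estimated correlation), and the gene that rose was Kdm5d, from TfamAKO 4 and 5. Its median was -0.07 and its mean 0.66.

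Of the 43 lists, 30 passed camera at the preset correlation, 21 upward and 9 downward, and 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. The exact permutation test of list scores called 31 lists and fry 29. Neither compares a list with other genes, and 37.4% of all tested genes were called, so these counts do not set the lists apart. Other splits of the libraries into 5 and 5 called a median of 20 lists at the preset correlation and at most 30. The split with 30 exchanged 1 library of each genotype. The 77 drawn splits with 2 or 3 WT libraries on each side called a median of 14 and at most 29, so counts near that of the genotypes can arise between evenly mixed groups too.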

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

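The tests of explanations in this part were chosen after the results were seen, except the counts over other splits. In a group of 5 libraries, a library was singled out when its gap to the nearest other, divided by the group's range, exceeded Dixon's 95% critical value. Of 390 groups of values checked, 38 held such a library, and chance flags about 1 in 20. TfamAKO 1 gave 17 of the 38.

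TfamAKO 1 was farthest from the other TfamAKO libraries on the low side for Serpina3m (ratio of gap to range 0.833), Cdsn (0.860), Clca3a1 (0.721), Klk6 (0.763), Angptl4 (0.777), Plin2 (0.883), Clcf1 (0.848), Cx3cr1 (0.715), Tnfrsf1a (0.900), Nes (0.850), Ly6c2 (0.792), Rorb (0.735), Cdkn1a (0.868) and the monocyte and neutrophil score (0.795). It was highest for Slc7a10 (0.782), Rlbp1 (0.724) and the choroid plexus score (0.776).

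TfamAKO 5 was lowest for Rtl3 (0.815), Mfge8 (0.783), Gpnmb (0.756), Nr4a2 (0.750), Tdo2 (0.711) and Cdhr1 (0.728). The mtDNA maintenance score was lowest in TfamAKO 4 (0.740), and Tfam was lowest in TfamAKO 3 (0.791) and in WT 3 (0.823). WT 1 was lowest for the A2-type astrocyte (0.750), endothelial (0.822) and spillover scores (0.764) and for Pfkfb3 (0.820). WT 2 was lowest for the dentate gyrus score (0.803), Homer1 (0.859) and Ly6c2 (0.831), and highest for Lonp1 (0.760), Enpp6 (0.829) and S100a4 (0.723). WT 4 was highest for the cholesterol synthesis score (0.837), and WT 5 lowest for Hsd17b7 (0.804).

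TfamAKO 1 stood 60.1% of the way from the WT mean to the mean of the other TfamAKO libraries on the first component. A mixture with wild-type RNA would bring every list to the same share of its change. TfamAKO 1 reached 79.0% of the change for stress response genes, 65.1% for interferon-stimulated genes, 47.6% for pan-reactive astrocyte genes and 39.8% for pan-neuronal genes, over genes called without it, and least for inhibitory neuron genes. Stress response genes were 58.0 percentage points above inhibitory neuron genes, a pair chosen after the values were seen. The same lists differed by -69.0 points in another TfamAKO library, TfamAKO 4, so mice differ by as much. These shares therefore cannot tell a mixture from a milder or later response. Other measures, picked after their values were seen, bear on a mixture. Relative to the WT mean, the cholesterol synthesis score was 0.18 in TfamAKO 1, -0.02 to 0.04 in WT and -0.37 to -0.12 in the other TfamAKO libraries. The mtDNA share of TfamAKO 1 was 4.18%, within the 4.06% to 4.71% of the others. A mixture would place both between the groups, which argues against it as the whole account. In counts thinned to 1 depth TfamAKO 1 stayed at 60.4% on the first component, below the 88.6% of the next library, which argues against depth.

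Choroid plexus transcripts were high in WT 3, 4 and 5. Of the 15 fallen genes of the list, 1 (Kl) had every WT library above every TfamAKO library. A candidate explanation is choroid plexus carried into some WT dissections, because 1 source keeps its genes in 1 ratio. Between WT 3, 4 and 5, the excess of the other 14 fallen genes over TfamAKO kept the ratio of Ttr within 2 SE for each pair, with a largest difference of -0.15 on the log2 scale (WT 3 against WT 5). A difference between mice in choroid plexus itself would keep the ratio too and stays open. A difference by genotype alone would also keep it, but would set WT 1 and 2 with the other WT libraries. Relative to the WT mean, the list score was -2.48 in WT 1, -1.28 in WT 2 and 0.99 to 1.44 in WT 3, 4 and 5. In TfamAKO it ran from -1.91 to -1.41. WT 1 lay below TfamAKO and WT 2 just above it, which argues against genotype as the whole account.

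Neuronal lists were lower in TfamAKO. A lower share of neuronal RNA with all else unchanged would raise the markers of other cell types alike. The homeostatic microglia score rose more than the oligodendrocyte and myelin score, by 0.39 on the log2 scale (two-sided exact permutation p = 0.00794, adjusted p = 0.0317 over 4 such contrasts), which argues against that as the whole account, while a gain of microglia beside it stays open. The contrasts of endothelial (adjusted p = 0.0794), precursor (0.0847) and pericyte scores (0.190) with the oligodendrocyte and myelin score did not pass. The oligodendrocyte and myelin list holds Enpp2, also a choroid plexus gene. It was at 1267 to 1966 CPM in WT 3, 4 and 5 and at 117 to 253 CPM elsewhere, which widens all these contrasts. They were not repeated without Enpp2, so their size is uncertain. After trends with transcript length and GC content were removed within each library, the pan-neuronal median was -0.42 (SE 0.06), from -0.37 before, which argues against such a trend. Loss of neurons and lower transcript levels in neurons were not told apart here.

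Other splits of the 10 libraries into 5 and 5 bear on the counts, with 100 of the 126 possible splits drawn, the real one included. For genes past the threshold, 1 of the 100 gave as many, the real split with 6048 against at most 2183 in another. The same held for the 3369 genes higher and the 2679 genes lower, with 1 split of 100 each and at most 1308 genes in 1 direction elsewhere. A share of 1 in 100 is the smallest these draws can give, so an arbitrary split is an unlikely source of these counts. The other splits hold the genotype difference within their groups, which widens their spread and lowers their counts. They do not bear on libraries that differ in 1 genotype only, such as those with Y-linked or choroid plexus transcripts. For gene lists past the preset-correlation camera test, 2 of the 100 gave 30 or more, and the highest other split also gave 30. The 99 other splits called a median of 20 lists, and the 96 with 0 genes past the threshold called up to 30. The other split with 30 kept 4 libraries of each genotype together, and the 22 splits of that kind had a median of 26. The 77 splits with 2 or 3 WT libraries on each side had a median of 14 and at most 29. The number of lists called at the preset correlation is therefore weak evidence by itself, although the share of splits is under the threshold of 0.05.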

How the results depend on the processing

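Alternatives with the authors' factors, the libraries with Y-linked or choroid plexus transcripts left out, and those 2 measures as covariates were chosen after seeing the data. Against 6048 genes past the threshold, the alternatives gave 2752 to 8911. The glmTreat test against a 1.2-fold change, which by construction asks for more, gave 2770 genes, 1961 higher and 809 lower. Without the libraries holding choroid plexus transcripts (WT 3, 4 and 5, chosen by over 1000 CPM of Ttr) there were 2752 genes, 2002 higher and 750 lower, of which 2549 were shared with the 6048. That fit has 2 WT libraries. Genes lower numbered 1672 with Y-linked expression as covariate, 1772 with the choroid plexus score as covariate and 4313 with limma-voom sample weights, and the cause was not tested. Leaving out each library gave 4828 to 7094 genes, 2839 to 3800 higher and 1989 to 3294 lower. Upper-quartile scaling gave 50.2% of calls higher, against 55.7%.

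Tfam lost its call with log2 fold changes of -0.40 under glmTreat (adjusted p = 0.179), -0.28, -0.28 and -0.28 for the normalized values with pseudocounts of 1, 0.5 and 5 in limma, -0.28 with the authors' factors as offsets, and -0.43 without TfamAKO 4 and 5, and the cause was not tested. Leaving out each library gave -0.51 to -0.34. The mtDNA share differed by -1.67 to -1.21 percentage points when each library was left out.

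Gene lists past the threshold numbered 0 with an estimated correlation, 27 to 31 under the other alternatives and 29 to 32 when each library was left out. At the preset correlation the call was lost under some alternative by the lists of monocytes and neutrophils, dentate gyrus, CA1 and respiratory chain subunits, and gained by MHC class II, astrocyte identity and cholesterol synthesis. No pairing by replicate number was seen, since same-numbered libraries correlated at -0.14 to 0.07 in their deviations and no library correlated best with its own number. The labels give no litter or batch, so this does not exclude a pairing. With the replicate block, 5679 genes passed, 5395 of them shared with the 6048, and the mtDNA share differed by -1.44 with an exact sign-flip permutation p of 0.0625, the smallest that 5 pairs can give. Of 4598 alternatives for 149 named genes, 4488 kept direction and side of the threshold, 90 lost it, 11 gained it and 9 reversed. The reversed log2 fold changes were 0.55 for Kcne2, 0.0102 for Mfrp and 0.34 for Ecrg4 without the choroid plexus libraries. With the choroid plexus score as covariate they were 0.70 for Kcne2, 0.0169 for Slc4a5, 0.32 for Kcnj13, 0.20 for Cldn2, 0.17 for Mfrp and 0.25 for Ecrg4, and none of the 9 passed. Both alternatives take away choroid plexus signal by construction, since Kcne2, Slc4a5, Kcnj13 and Cldn2 are members of that score and the libraries were chosen by Ttr. Mfrp and Ecrg4 are not members but were high in the same libraries. Mfrp was at 48.6 to 77.7 CPM in WT 3, 4 and 5 and 0.430 to 2.75 CPM elsewhere, and Ecrg4 at 30.4 to 55.3 and 1.23 to 3.05 CPM. These reversals therefore do not bear on the processing. The choroid plexus list was left out of the comparison of calls under both for the same reason, and lost its call without TfamAKO 4 and 5.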

Other observations

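The lists, genes and tests in this part were chosen after the data were seen, except Cdsn, Tgm1, Klk6 and Dsp, which the naming rule gave. The exact permutation test of a list score does not compare a list with other genes, and 37.4% of all tested genes were called in edgeR. Genes that the tumour suppressor p53 is known to regulate were higher in TfamAKO, with 16 of 20 tested genes rising and 1 falling (median log2 fold change 1.03). The cell cycle inhibitor Cdkn1a went from 27.3 ± 5.14 CPM in WT to 178 ± 82.5 CPM in TfamAKO (log2 fold change 2.70 ± 0.40, edgeR adjusted p = 0.000316), and Ccng1 (1.39 ± 0.12), Phlda3 (2.17 ± 0.18) and Eda2r (4.79 ± 0.31) rose on the log2 scale. Of the 20 genes, 3 belong to lists fixed earlier. The list score differed by 1.38 (two-sided exact permutation p = 0.00794, adjusted p = 0.00992 over 5 such lists), while camera with an estimated correlation gave adjusted p = 0.163.

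Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation outside mitochondria, gave 15 of 20 tested genes higher and 0 lower, with Eprs (log2 fold change 1.16 ± 0.06, edgeR adjusted p = 6.98e-08), Lars (0.85 ± 0.06) and Wars (0.83 ± 0.06) among them. Of the mitochondrial synthetases, 2 of 17 rose and 5 fell, with a median of 0.04 and a list score difference of -0.05, which differ in sign. With an estimated correlation, camera gave adjusted p = 0.163 for the cytosolic and 0.530 for the mitochondrial set, while the exact permutation test of the list score gave adjusted p = 0.00992 for each, with a difference of 0.36 for the cytosolic set. For mitochondrial ribosomal proteins, 3 of 57 rose and 11 fell (exact permutation p of the list score 0.159).

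Cdsn and Tgm1, which serve the skin barrier, and Klk6 rose in TfamAKO. Of 10 tested genes of skin structure 0 rose and 4 fell (median log2 fold change -0.57). This list did not pass camera (adjusted p = 0.0543 over 5 such lists, and 0.168 with an estimated correlation), while its list score had an exact permutation adjusted p of 0.00992. The dentate gyrus gene Dsp is among these 10.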
